A study of Homo sapiens with 21 samples.

How the data were processed

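RNA of 21 BEAS-2B libraries was measured by sequencing, 3 in each of 7 groups: an unirradiated control at passage 50, and single-exposure and multiple-exposure cells at passages 10, 30 and 50. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.2.1.0, HTSeq 0.11.2 and the human genome build hg38 were used, without a statement of what each tool did. The authors deposited a table of raw counts per gene for 19918 genes, and a table of FPKM for the same genes. The tool that made the FPKM is not given in the sources used here, and neither are the strand setting and the handling of reads that match several genes. Counts of genes with near-identical copies (ribosomal protein genes, histone genes, CXCL5 and CXCL6) are therefore less certain. The deposited FPKM were checked against the counts: relative to the median of the same gene, the ratio of FPKM to count lay between 0.92 and 1.076 in most libraries with high counts (lower and upper 5% left out), and 109 FPKM values were 0 where the count was over 10. Raw reads were not analysed here.

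Genes were matched to the RefSeq annotation of GRCh38 by GeneID, which gave a position for 19583 of them (98.3%) and left 335 without one. Gene names that spreadsheet software had turned into dates (28) were restored from their GeneID. Libraries held 20671475 to 22017293 counts, and the 10 most abundant genes took 2.81% to 4.8% of them. Groups were taken from the labels. Their extraction protocol speaks of heart samples, although each library is labelled as BEAS-2B cells. The labels give no sequencing batch and do not say whether libraries of a group came from separate cultures, and the replicate number was not treated as pairing libraries.

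Counts were fitted with edgeR 4.0.16 in R 4.3.3 as 1 quasi-likelihood model of all 21 libraries and 7 groups, with TMM normalization and the default low-count filter, which left 13361 genes. The common biological coefficient of variation was 0.236, the residual degrees of freedom 14 and the prior degrees of freedom 5.41. There were 12 tests: 6 groups against the control, multiple against single exposure at each passage, passage 50 against passage 10 in each regime, and the interaction of regime and passage. p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05, and log2 CPM used a prior count of 2. CPM are given as mean ± SD over 3 libraries. The SE of a log2 fold change is its absolute value divided by the square root of its quasi-likelihood F statistic. It is therefore approximate, above all for genes near 0 counts in a group. Where a group had 0 counts, a fold is given as at least a value computed with a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its 95% counting interval.

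Gene lists written before the data were examined (21 with enough genes tested) were tested with camera of limma 3.58.1, with the preset correlation of 0.01 between genes, with an estimated correlation, and with fry, adjusted over the lists of a comparison. fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Lists of cancer-testis genes and of mitochondrially encoded genes were searched for as well. Members were also counted with p-values adjusted over the list alone. Camera was run on 23 chromosomes, without chromosome Y, and on 297 pathways of 10 to 300 genes annotated in the deposited table. A chromosome was known for 13299 of the genes tested, chromosome Y included. The overlap of comparisons that share the control was set against 20 simulated pairs of unchanged groups.

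Named genes followed a rule fixed in advance. In the 5 main comparisons these were protein-coding genes past the threshold with a mean of at least 10 CPM in the higher group and ranges that do not overlap (expected by chance for 10% of genes with 3 against 3 libraries), the 6 largest changes in each direction; up to 2 members in each direction of each list, with at least 5 CPM; and a panel of 22 genes whatever their result. For the interaction, 4 in each direction were taken and the criterion on ranges was dropped. Some genes the rule names are not reported. The text describes part of the others, mostly those whose call did not depend on 1 library. Comparisons of passages 10 and 30 with the control name only panel genes and genes already named.

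Alternatives were no low-count filter (16979 genes), at least 1 CPM in 3 libraries (12643 genes), RLE normalization, DESeq2 1.42.0, a fit of only the groups compared, replicate number as an additive term, limma-trend on log2 FPKM with pseudocounts of 0.1 and 1, and leaving out each library in turn. Chosen after seeing the data were offsets for GC content and transcript length (loess with a span of 0.3, 13238 genes with both values), 2 surrogate variables from sva 3.50.0, a fit without single-exposure replicate 1 at passage 50, and the pathway tests. The offsets were first run without centring each library's trend, which moved all fold changes, and the centred version was chosen after that shift was seen; both are reported. A sign change counts as reversed only if the value or its alternative is past the threshold.

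The model was tested on simulated data built from these libraries' means and dispersions. Between single-exposure and control cells at passage 50, 6%, 43.3% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold were called in the right direction, with 4 unchanged genes called; for the interaction these shares were 1.5%, 9% and 62.1%. A simulated 1.5-fold change of 1 list was found with an adjusted p of 6.2e-26 and 0 other lists past the threshold, and a simulated shift of -0.4 of chromosome 5 was measured as -0.41. The simulated genes varied independently of each other. These runs therefore cannot show how often list or chromosome tests pass falsely where genes vary together.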

Results

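Total RNA of BEAS-2B cells, an immortalised line of human bronchial epithelium, was sequenced after exposure to α-particles from an americium source, in 7 groups of 3 libraries. Single-exposure cells had received 0.5 Gy at once and were sampled at passages 10, 30 and 50, about 3, 9 and 15 weeks after irradiation ended. Multiple-exposure cells had received 25 doses of 0.02 Gy, each lasting 9 seconds and spaced 3 days apart, and were sampled at the same passages. Unirradiated control cells were sub-cultured in parallel and carry the label of passage 50 only. The comparisons at passage 50 are therefore matched in passage label, while those of passages 10 and 30 with the control are not. Sampling times are counted from the end of irradiation, and the 25 doses were spread over time. Equal labels therefore need not mean equal time in culture, and a difference in culture time cannot be told apart from the exposure regime. Each library held 20671475 to 22017293 counts on genes, and 13946 to 14816 genes had at least 1 count. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 5.06, control replicates 1 and 2). The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

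The control stood apart from every irradiated library. On the first principal component of log2 CPM, which held 54.7% of the variance, the 3 control libraries lay between -136.9 and -134.8 and the 18 irradiated libraries between 12.4 and 36.6. Within the single-exposure group at passage 50, replicate 1 deviated from its group mean along GC content (Spearman's rho 0.89 across genes, which are not independent replicates). The mirrored values were -0.83 and -0.86 in the other libraries of that group, and the remaining 18 libraries lay between -0.26 and 0.35.

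**Figure D1:**
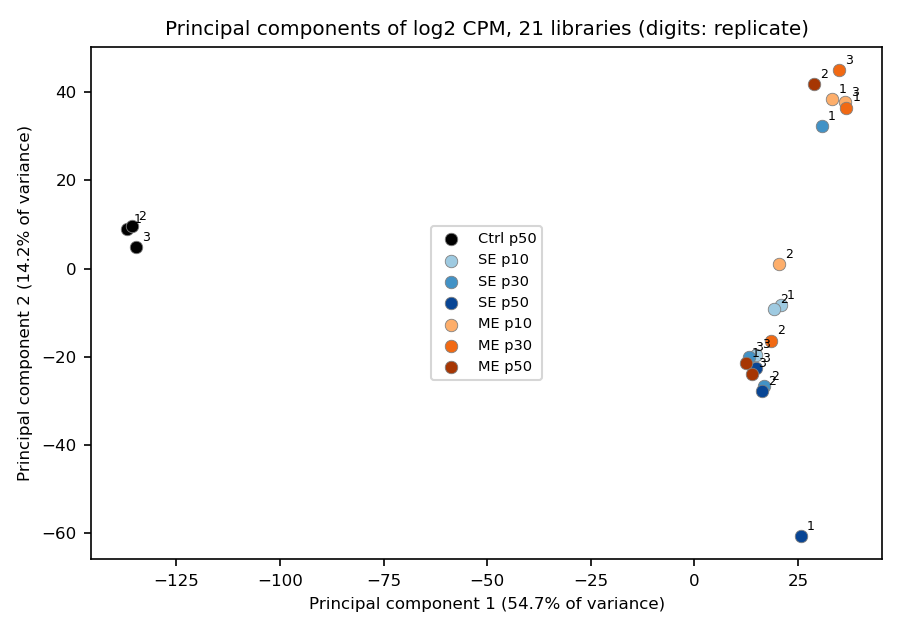
First against second principal component of log2 CPM for the 21 libraries (axes in component units, digits give the replicate number). The control libraries lie between -136.9 and -134.8 on the first component and every irradiated library at 12.4 or above.

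The comparison of single-exposure cells with the control at passage 50 asks how cells given 1 dose of 0.5 Gy differed from unirradiated cells with the same passage label. The genes COL5A2, COL1A1 and GREM1 were far higher in the irradiated cells. COL5A2, a chain of the fibrillar type V collagen (GeneID 1290; chromosome 2, 189031898 to 189441111 on GRCh38), reached 652 ± 3.39 CPM (SD, n = 3) against 2.58 ± 0.313 CPM, a log2 fold change of 7.98 (SE 0.27, adjusted p = 2.2e-14). COL1A1, a chain of type I collagen (GeneID 1277; chromosome 17, 50184101 to 50201631), reached 1520 ± 423 against 19.6 ± 3.77 CPM (log2 fold change 6.28, SE 0.26, adjusted p = 3e-13). GREM1, a secreted antagonist of bone morphogenetic proteins (GeneID 26585; chromosome 15, 32718004 to 32745106), rose from 0.968 ± 0.264 to 353 ± 100 CPM (8.50, SE 0.37, adjusted p = 5.35e-13). FOXA1 and S100A2 fell, although airway markers as a list did not pass the set test, camera with a preset correlation (adjusted p = 0.233). FOXA1, a transcription factor of endodermal epithelia (GeneID 3169; chromosome 14, 37589552 to 37595249), went from 27.1 ± 9.08 to 0.16 ± 0.0713 CPM (-7.35, SE 0.43, adjusted p = 5.37e-11). S100A2, a calcium-binding protein of basal epithelial cells (GeneID 6273; chromosome 1, 153561108 to 153565844), went from 166 ± 25.2 to 5.7 ± 1.83 CPM (-4.86, SE 0.32, adjusted p = 3.37e-10).

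By the edgeR quasi-likelihood test, 4320 of 13361 genes passed an adjusted p of 0.05, 2437 higher and 1883 lower, of which 1546 and 925 changed at least 2-fold. Among the largest changes, NLRP2, an inflammasome-related gene, and ADAM33, a metalloprotease gene, had 0 counts in the control and were at least 286-fold and at least 205-fold higher (14 ± 2.29 and 10.1 ± 2.43 CPM). PTPRN, a receptor-type phosphatase gene, had 3 counts over the 3 control libraries and 38.1 ± 9.08 CPM in single-exposure cells (ratio 775, 95% counting interval 265 to 3760). These floors and intervals cover counting error only. ZNF532, a zinc finger gene, rose from 0.0648 ± 0.0255 to 59.9 ± 18.7 CPM. On the other side, CXorf57 was at least 391-fold lower. The glypican genes GPC6 and GPC4 had 2 counts each in the irradiated libraries (ratios 917 and 828, intervals 253 to 7580 and 229 to 6840). The membrane protein genes TMEM47 and ITM2A fell from 101 ± 6.87 to 0.175 ± 0.179 and from 98.6 ± 25 to 0.207 ± 0.108 CPM. With GC and length offsets that were not centred, which moved the median of all genes by -0.117, the split was 2103 higher and 3502 lower. With only the groups compared in the fit, 2737 genes passed.

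**Figure D2:**
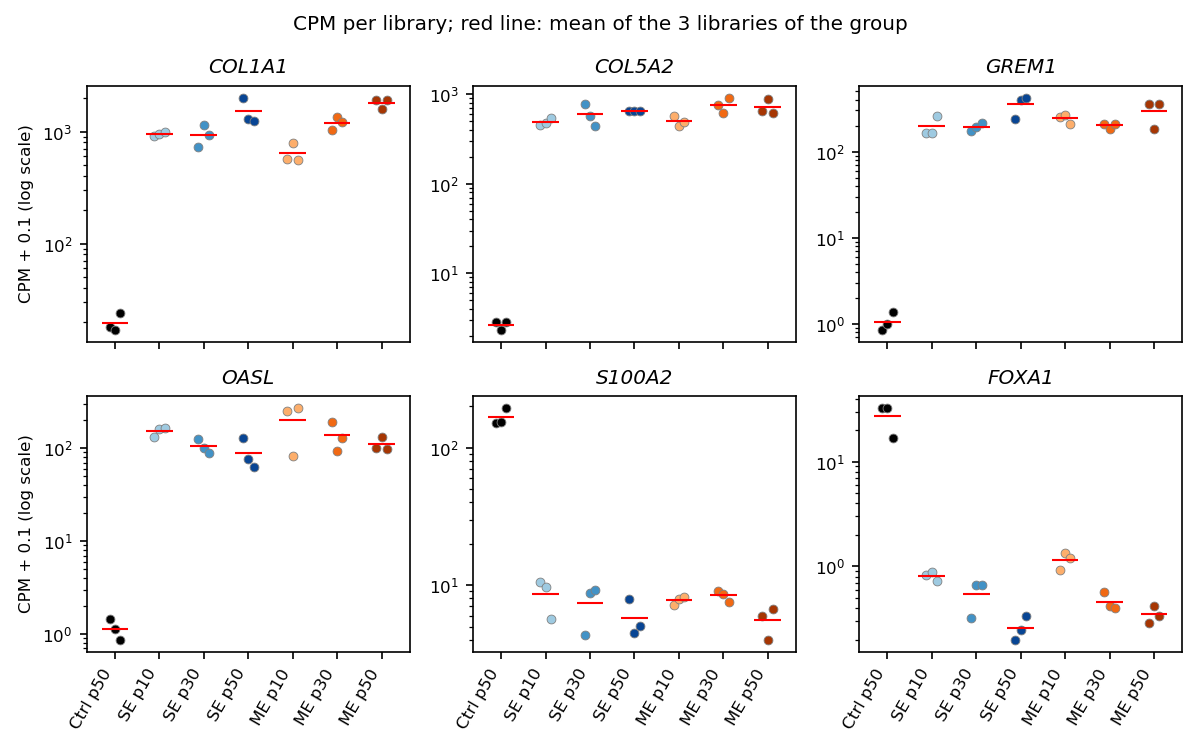
CPM + 0.1 on a log axis for 6 genes in each library of the 7 groups (points), with the mean of the 3 libraries as a red line. COL1A1, COL5A2, GREM1 and OASL lie higher, and S100A2 and FOXA1 lower, in all 18 irradiated libraries than in the 3 control libraries.

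Genes of fibrillar matrix and matrix enzymes rose as a group: 22 of 44 were higher and 7 lower (23 and 7 adjusted over the list alone; set test adjusted p = 2.42e-05, and adjusted p = 0.051 with an estimated correlation). FBLN2, a matrix glycoprotein, rose from 0.998 ± 0.00955 to 221 ± 86 CPM, while the elastic fibre gene FBLN5 and the gelatinase gene MMP2 fell (log2 fold change -2.16 and -2.10, adjusted p = 2.2e-06 and 7.52e-08). Of 37 ECM-receptor ligands 16 were higher and 8 lower (20 and 9 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.309 with an estimated correlation). THBS2, a matricellular thrombospondin, rose from 2.23 ± 0.0992 to 473 ± 10.9 CPM, and the basement membrane collagens COL4A1 and COL4A2 rose by 1.73 and 1.87 on the log2 scale, whereas the laminin chains LAMA4 and LAMA3 fell (-3.94 and -1.95). Of 26 ECM receptors 11 were higher and 6 lower (12 and 6 adjusted over the list alone; adjusted p = 0.608, and adjusted p = 0.00203 by fry, upwards). ITGB5 and ITGA7 rose (1.51 and 1.47), and ITGA1, ITGB8 and ITGB4 fell (-2.78, -2.43 and -1.22). The study's title names the ECM-receptor pathway, so the direction of these ligand and receptor lists is not independent evidence. In the deposited table's own annotation of that pathway, a test added after the data were seen, 26 of 61 genes were higher and 13 lower (adjusted p over 297 pathways = 0.187). Fibroblast markers were higher for 4 of 7 genes and lower for 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.309 with an estimated correlation). The receptor gene PDGFRB rose from 4.23 ± 0.607 to 53.4 ± 17.7 CPM, and the protease gene FAP fell from 25.3 ± 3.23 to 0.989 ± 0.551 CPM. Without a low-count filter the ligand and fibroblast calls ended (adjusted p = 0.0864 and 0.545), as did the ligand call with GC and length offsets (0.0687).

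Senescence secretome and cytokine genes rose, with 19 of 33 higher and 3 lower (22 and 3 adjusted over the list alone; adjusted p = 5.1e-05, and adjusted p = 0.309 with an estimated correlation). The chemokine gene CCL5 went from 0.0984 ± 0.0509 to 20.4 ± 4.3 CPM, and CXCL5 from 1 count to 6.12 ± 1.93 CPM (ratio 375, interval 66.8 to 14800), while the growth factor binding protein gene IGFBP5 and the cell cycle inhibitor gene CDKN2B fell (-2.60 and -1.39). Cytosolic ribosomal protein genes were lower for 13 of 74 and higher for 2 (10 and 1 adjusted over the list alone; adjusted p = 0.0372, and adjusted p = 0.911 with an estimated correlation), led by RPL10 and RPS6 (-1.12 and -0.98). That call ended without control replicate 3 (0.114), without single-exposure replicate 2 (0.0647) or 3 (0.177), with GC and length offsets (0.0687) and by fry (0.12).

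In the following lists members moved both ways and camera was not passed with either correlation. By fry, which asks whether a list moves one way on balance and compares it with no other genes, 7 of the lists not passed by camera were passed besides the receptors. Epithelial (adjusted p = 6.16e-06), mesenchymal (1.07e-05), cardiomyocyte (3.24e-05), interferon (0.00936), TGF-β (0.0131) and unfolded protein response genes (0.0133) were higher, and airway markers lower (5.28e-05). Without single-exposure replicate 1 the mesenchymal and cardiomyocyte lists also passed camera (0.049 each), as did the unfolded protein response without a low-count filter (0.0444). Of 45 interferon-stimulated genes 18 were higher and 8 lower (18 and 8 adjusted over the list alone; adjusted p = 0.125). OASL rose from 1.05 ± 0.294 to 89.1 ± 35.5 CPM, and the viral tethering factor BST2 fell from 83.5 ± 16.3 to 4.06 ± 1.15 CPM. Of 34 mesenchymal genes 12 were higher and 5 lower (13 and 7 adjusted over the list alone; 0.117), with the myosin light chain gene MYL9 up by 4.65 and the transcription factor gene ZEB1 down (-2.69). Of 29 epithelial junction and keratin genes 10 were higher and 5 lower (11 and 8; 0.154). The tight junction gene CLDN1 and the cadherin gene CDH3 rose (5.35 and 2.35), and TJP1 and DSG2 fell (-1.33 and -1.30). Of 20 TGF-β response genes 6 were higher and 3 lower (6 and 3; 0.66), LTBP2 rising (4.26) and ID1 and LMCD1 falling (-2.64 and -2.18). Of 30 p53 targets 6 were higher and 2 lower (6 and 2; 0.669), FDXR rising (1.09) and EDA2R and CCNG1 falling (-4.33 and -1.05). Of 50 DNA damage and repair genes 4 were higher and 4 lower (3 and 2; 0.66), FANCA and RNF8 rising (1.32 and 0.64) and ATM and RAD50 falling (-1.16 and -1.10, adjusted p = 0.0115 and 0.03). In single-exposure replicate 1, the library that deviated along GC content, RAD50 was at 15.6 CPM and ATM at 24.7 CPM, against 86.2 and 92.7 CPM and 81.6 and 98 CPM in replicates 2 and 3. Without replicate 1 the log2 fold changes were -0.63 (adjusted p = 0.0131) for RAD50, -0.75 (0.0202) for ATM and 0.65 (0.00374) for FDXR. The RAD50 call ended without control replicate 2 (0.0631) or 3 (0.084), and those of FDXR, ATM and RAD50 with only the groups compared (0.0501, 0.114 and 0.215). Of 50 cell cycle genes 8 were higher and 1 lower (5 and 0; 0.946), MYBL2 and CCND1 rising (1.52 and 1.36). The lower gene CDC25C (-0.41, adjusted p = 0.044) lost its call without any control replicate and without single-exposure replicate 2 or 3 (0.0664 to 0.12), and with RLE normalization (0.0621), among other settings.

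Smaller numbers passed in the remaining lists, with the counts adjusted over the list alone in brackets. The unfolded protein and amino acid response had 8 of 30 higher and 1 lower (8 and 1; adjusted p = 0.171), NRF2 antioxidant genes 3 and 3 of 29 (3 and 3; 0.66), hypoxia and glycolysis genes 3 and 4 of 36 (3 and 2; 0.669) and cholesterol synthesis genes 3 and 0 of 25 (1 and 0; 0.327). Airway basal, secretory and ciliated markers had 3 and 3 of 9 (3 and 3; 0.233), cardiomyocyte markers 4 and 1 of 9 (4 and 1; 0.0981), leukocyte and endothelial markers 1 and 1 of 8 (1 and 1; 0.944) and histone genes 2 and 1 of 14 (2 and 0; 0.944). The median, mean and test of a list differed in sign for airway markers (0.43, -0.05, down), TGF-β response genes (-0.02, 0.18, up) and histone genes (-0.09, 0.36, down). The cardiac transcription factor gene NKX2-5 had 2 control counts and 29.9 ± 12.4 CPM in single-exposure cells (ratio 911, interval 252 to 7530). The extraction protocol in the labels speaks of heart samples, while every library is labelled as BEAS-2B, so what the cardiac transcripts stem from is not settled by the labels. Of 25 cardiomyocyte markers, 10 had at most 3 counts in every library, and the highest mean over all libraries was 17.2 CPM. The macrophage marker CD68 rose by 0.86. The haemoglobin gene HBB, a marker of blood, was listed lower, but its control level came from replicate 2 alone, and its adjusted p without that library was 0.325. Of 32 cancer-testis genes 2 could be tested, 26 had at most 3 counts in every library, and the highest mean was 0.592 CPM. The table holds 0 mitochondrially encoded genes.

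Of the panel of 22 genes fixed in advance, the kinase inhibitor gene CDKN1A, a p53 target, had a log2 fold change of 0.89 (SE 0.30, adjusted p = 0.0261), and the p53 regulator MDM2 one of 0.35 (SE 0.27, adjusted p = 0.339). MDM2 passed with GC and length offsets (0.0285) and without single-exposure replicate 1 (0.0269). The CDKN1A call ended with GC and length offsets (0.126) and without control replicate 1 (0.0866), control replicate 3 (0.0692) or single-exposure replicate 1 (0.125). VIM, CDH2, TNC, THBS1, ITGAV, MYC and EGFR did not pass, and CDH1 was too low to test, with at most 10 counts in any library.

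The same question for 25 doses of 0.02 Gy gave a profile led by the same kinds of genes. In multiple-exposure cells at passage 50, COL5A2 stood at 713 ± 149 CPM and COL1A1 at 1810 ± 186 CPM (log2 fold change 8.11 and 6.53, adjusted p = 1.7e-14 and 2.18e-13), GREM1 at 298 ± 100 CPM and THBS2 at 320 ± 23.2 CPM. ITGA4, the α4 integrin chain that binds fibronectin and VCAM1 (GeneID 3676; chromosome 2, 181457205 to 181538940), had 0 counts in the control and 20.1 ± 1.5 CPM, at least 409-fold higher. FOXA1 and S100A2 fell to 0.249 ± 0.068 and 5.47 ± 1.44 CPM, and EYA1, a developmental transcription cofactor gene, was at least 1170-fold lower, from 54.6 ± 3.81 CPM. By the edgeR test 3891 genes passed, 2282 higher and 1609 lower, of which 1530 and 806 changed at least 2-fold. With the offsets that were not centred, which moved the median of all genes by -0.154, the split was 2182 higher and 3519 lower.

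Among the lists, 22 of 33 secretome and cytokine genes were higher and 3 lower (24 and 3 adjusted over the list alone; adjusted p = 7.97e-06, and adjusted p = 0.272 with an estimated correlation). CXCL6 at 5.26 ± 1.63 CPM was at least 107-fold higher and the tumour suppressor gene CDKN2A was lower (-1.31, adjusted p = 0.000238). Fibrillar matrix genes had 22 of 44 higher and 9 lower (23 and 9 adjusted over the list alone; adjusted p = 4.67e-05, and adjusted p = 0.1 with an estimated correlation), with FBLN2 up by 7.63 and FBLN5 down (-2.46). Interferon-stimulated genes had 22 of 45 higher and 2 lower (23 and 4 adjusted over the list alone; adjusted p = 0.00294, and adjusted p = 0.374 with an estimated correlation). OASL was at 110 ± 18.1 and RSAD2 at 19.2 ± 9.18 CPM against 0.346 ± 0.261, while BST2 fell (-5.23). Fibroblast markers had 4 of 7 higher and 1 lower (4 and 1; adjusted p = 4.67e-05, and adjusted p = 0.134 with an estimated correlation). LUM, a collagen-binding proteoglycan, rose from 0.21 ± 0.115 to 9.49 ± 1.68 CPM, and FAP fell (-2.28). ECM-receptor ligands, again no independent evidence, had 14 of 37 higher and 8 lower (15 and 8 adjusted over the list alone; adjusted p = 0.00503, and adjusted p = 0.311 with an estimated correlation), and the receptors 9 and 4 of 26 (11 and 4; 0.276). The laminin chain LAMA4 and the integrin chains ITGB8 and ITGA1 were among those that fell (-4.35, -2.60 and -2.10). Cardiomyocyte markers had 5 of 9 higher and 1 lower (6 and 1; adjusted p = 0.0356, and adjusted p = 0.272 with an estimated correlation). Their median was 3.84, or 2.54 with genes absent from the control at their bound, and NKX2-5 was at 17.8 ± 3.87 CPM (ratio 542, interval 150 to 4480), with the same doubt about the tissue the protocol names. The cardiomyocyte call ended without control replicate 3 (0.0575) or multiple-exposure replicate 3 (0.0561). Without a low-count filter the ligand, fibroblast and cardiomyocyte calls ended (0.267, 0.283 and 0.327).

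By fry, ECM receptors (adjusted p = 3.86e-05), mesenchymal genes (8.97e-06), epithelial genes (0.000156) and TGF-β response genes (0.0236) were also higher and airway markers lower (2.1e-05), none of which passed camera with all libraries. Mesenchymal genes did so without multiple-exposure replicate 2 (0.0379, median -0.01). p53 targets did not pass camera or fry in these cells: of 30, 2 were higher and 3 lower (1 and 2 adjusted over the list alone; adjusted p = 0.537, and adjusted p = 0.642 by fry). EDA2R and CCNG1 fell (-5.15 and -1.05), while PLK3 (1.22, adjusted p = 0.0387) lost its call without any control replicate (0.0764 to 0.124), without multiple-exposure replicate 2 (0.306) and with GC and length offsets (0.0632). CDKN1A had a log2 fold change of -0.09 (SE 0.29, adjusted p = 0.855) and MDM2 one of -0.08 (SE 0.27, adjusted p = 0.851). DNA damage and repair genes had 7 of 50 higher and 2 lower (5 and 0; 0.733), FANCA and RNF168 rising (1.20 and 0.94). The lower genes ATM (-0.97, adjusted p = 0.0345) and CHEK1 (-0.53, adjusted p = 0.0421) lost their calls when libraries were left out, ATM without any of the 6 (0.0528 to 0.104) and CHEK1 without any but multiple-exposure replicate 2 (0.077 to 0.136). Cell cycle genes had 6 and 1 of 50 (5 and 0; 0.733), CCND1 and MYBL2 rising (1.32 and 1.19). The call of CDC25C (-0.44, adjusted p = 0.033) ended without control replicates 1 and 2 (0.0907 and 0.0995) and multiple-exposure replicate 2 (0.182). Desmoplakin, DSP, a desmosome component, rose by 2.51, CLDN1 by 5.17, and the splicing regulator ESRP2 and the keratin KRT7 fell (-2.78 and -1.65), with 9 of 29 epithelial genes higher and 5 lower (9 and 6; 0.516). No cholesterol synthesis gene passed by edgeR (0 of 25, and 0 adjusted over the list alone).

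Single-exposure and multiple-exposure cells at passage 50 shared many of their differences from the control. Both edgeR tests called 3009 genes, 1805 higher and 1201 lower in both and 3 in opposite directions. Independent lists of these sizes would share 416.2 higher and 226.8 lower, and 20 simulated pairs of unchanged groups against the same controls shared 0 calls. The simulated libraries varied independently and gave almost no calls, so sharing none was bound to follow. The log2 fold changes correlated with r = 0.941 across genes, against 0.507 in the simulation, and their covariance was 3.006 against 0.066, a difference of 2.94. The 3 controls cannot be divided into groups of 2 libraries each, so part of the excess may come from the shared controls.

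Against the same control, 3571 genes passed in single-exposure cells at passage 10 (2046 higher, 1525 lower), 3908 at passage 30 (2189 and 1719), and in multiple-exposure cells 4930 at passage 10 (2735 and 2195) and 5012 at passage 30 (2928 and 2084). In these comparisons irradiation and passage cannot be told apart. Over all 6 comparisons with the control, 1409 genes were higher and 848 lower each time, of 7303 called at least once. Independent lists of these sizes would share 0.47 and 0.085 genes, and in 20 simulations of 6 unchanged groups against the same controls 0 genes were called each time. The simulated libraries varied independently, and at most 1 gene was called in any comparison of a simulation. A shared count of 0 was therefore bound to follow, and controls that deviate together were not simulated. All 6 comparisons use the same 3 control libraries, so part of this agreement may come from them. COL4A1 was 2.12-fold to 2.55-fold higher in these earlier groups (highest adjusted p = 8.28e-06), and MDM2 passed only in multiple-exposure cells at passage 10 (log2 fold change 1.00, adjusted p = 0.00738). With only the groups compared, single-exposure cells at passage 10 gave 6734 calls. The offsets that were not centred moved the median of all genes by -0.171 to -0.152 here and turned the splits to 1993 higher and 3573 lower, 2132 and 3470, 2598 and 4318, and 2703 and 4201, in the order given.

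Genes of whole chromosomes shifted together by the set test, in comparisons with the control and in comparisons without it. Of 26 tests that passed in the 5 main comparisons, 7 were against the control and 19 were not. In single-exposure cells at passage 50, the median log2 fold change was -0.47 on chromosome 5 (231 of 608 genes lower, 61 higher; set test adjusted p = 2.08e-05), -0.33 on chromosome 14 (adjusted p = 0.0198), 0.19 on chromosome 3 (0.0371) and 0.44 on chromosome 22 (0.000131). With an estimated correlation their adjusted p lay between 0.621 and 0.861. The chromosome 3 call ended without single-exposure replicate 2 (0.0809) or 3 (0.115), and the chromosome 22 call with GC and length offsets (0.0513). In multiple-exposure cells at passage 50, chromosomes 5, 14 and 3 had medians of -0.46, -0.29 and 0.25 (adjusted p = 3.16e-05, 0.0113 and 0.0103, and adjusted p = 0.577 with an estimated correlation). Chromosomes 3, 5 and 14 passed with the same signs in all 6 comparisons with the control. These comparisons share the 3 control libraries, so 1 deviation of the controls would appear in each of them, and the repeats are not independent. In those at passages 10 and 30 their adjusted p was 0.588 to 0.677 with an estimated correlation.

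Among the comparisons without the control, 8 chromosomes passed between the regimes at passage 50, with medians from -0.20 on chromosome 22 (adjusted p = 2.13e-07) to 0.21 on chromosome 4 (7.32e-06). Without single-exposure replicate 1, the library that deviated along GC content, chromosome 1 alone of these passed with the same sign (adjusted p = 0.0199). With all libraries its median was 0.11 (adjusted p = 0.0338, and adjusted p = 0.011 with an estimated correlation). That call in turn ended without single-exposure replicates 2 and 3 (0.0871 and 0.116) and multiple-exposure replicates 1 and 3 (0.0821 and 0.0904). Between passages 50 and 10 of single-exposure cells 9 passed. Of these, chromosomes 7 and 21 (medians 0.17 and 0.13, adjusted p = 0.000314 and 0.00338) passed without each of the 6 libraries (at most 0.00958 and 0.0471), with GC and length offsets (1.01e-06 and 0.000856) and with an estimated correlation (adjusted p = 0.0372 for both). The other 7 ended without single-exposure passage 50 replicate 1 (0.246 to 0.979), with the offsets (0.431 to 0.966) and with an estimated correlation (adjusted p = 0.4 to 0.607). Chromosome 11, which did not pass, did so without that library (median -0.15, adjusted p = 6.11e-07) and with the offsets (5.12e-05). Chromosome 1 passed there only with an estimated correlation (median -0.08, adjusted p = 0.0411, against 0.106 with the preset one). In multiple-exposure cells chromosomes 7 and 13 passed between these passages (medians 0.11 and -0.17, adjusted p = 0.0341 and 0.00956, and adjusted p = 0.703 and 0.871 with an estimated correlation). Both calls ended without passage 10 replicate 2 (0.0697 for each), and that of chromosome 7 without passage 50 replicate 2 (0.116).

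**Figure D3:**
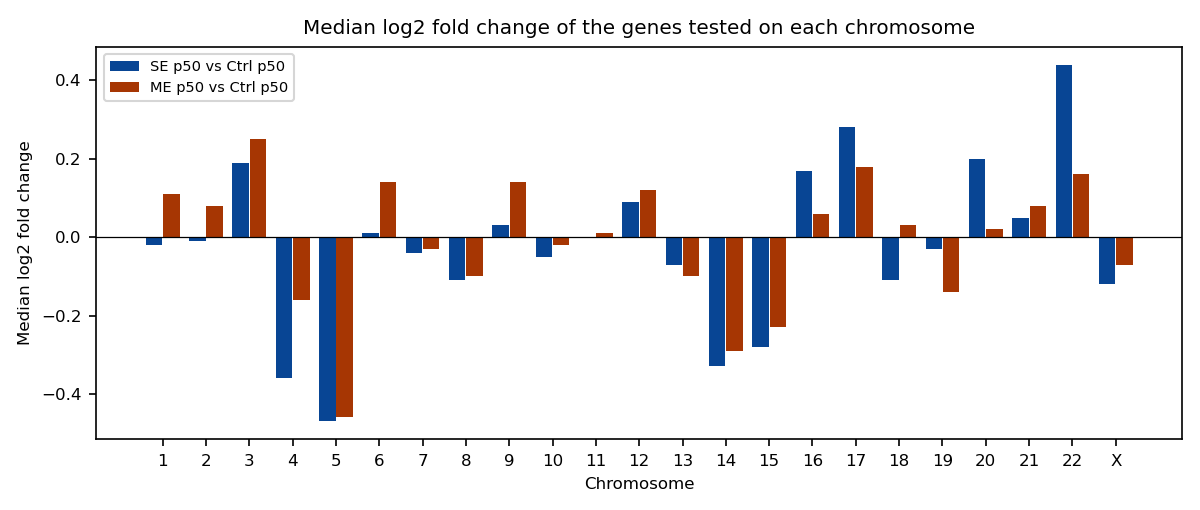
Median log2 fold change of the genes tested on each chromosome, for single-exposure (blue bars) and multiple-exposure cells (brown bars) against the control at passage 50. Chromosome 5 has the lowest bars that passed the set test, at -0.47 and -0.46.

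Between the exposure regimes at passage 50, the integrin gene ITGA4 had the largest change among the genes named by the rule fixed in advance. It was 11.1-fold higher in multiple-exposure cells, at 20.1 ± 1.5 against 1.8 ± 0.775 CPM (log2 fold change 3.47, SE 0.34, adjusted p = 0.000109). SFMBT2, a polycomb-related gene, was higher (1.57, adjusted p = 0.00699). The laminin chain LAMA1 (-1.27, adjusted p = 0.00308), the neonatal Fc receptor gene FCGRT (-1.62, adjusted p = 0.00106), the membrane protein gene TMEM40 (-1.51, adjusted p = 0.00699) and the stathmin family gene STMN3 (-1.42, adjusted p = 0.00484) were lower. The fibroblast genes FAP and LUM were higher (2.39 and 2.18, adjusted p = 0.0377 and 0.0271). Their calls ended when single-exposure replicate 1 (0.138 and 0.094) or 2 (0.111 and 0.0941), or multiple-exposure replicate 1 (0.109 and 0.0794) or 3 (0.101 and 0.091), was left out. Fibroblast markers as a list had 3 of 7 higher (3 adjusted over the list alone; adjusted p = 0.00184, and adjusted p = 0.352 with an estimated correlation), and the call ended without single-exposure replicate 3 (0.061) and without a low-count filter (0.0511).

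Other lists passed with the preset correlation but not with an estimated one. Cholesterol synthesis genes were lower as a list (0 of 25 members past the test, and 0 adjusted over the list alone; median -0.43, adjusted p = 0.000644, and adjusted p = 0.748 with an estimated correlation), which ended without multiple-exposure replicate 2 (0.325) and by fry (0.603). Interferon-stimulated genes were higher (0 of 45, and 0 adjusted over the list alone; median 0.37, adjusted p = 0.00184, and adjusted p = 0.5 with an estimated correlation). p53 targets were lower (1 of 30, 4 adjusted over the list alone; adjusted p = 0.00184, and adjusted p = 0.352 with an estimated correlation), ending without single-exposure replicate 3 (0.0509). Epithelial genes (1 of 29 lower, 3 adjusted over the list alone) and leukocyte and endothelial markers (0 of 8, 1 adjusted over the list alone) were lower at adjusted p = 0.0246 and 0.0232, with adjusted p = 0.182 and 0.352 with an estimated correlation. Both calls ended without a low-count filter (0.296 and 0.131), without any single-exposure replicate (0.0606 to 0.107) and without multiple-exposure replicate 1 (0.0635 and 0.0546). The epithelial call also ended without multiple-exposure replicate 3 (0.131), and the leukocyte call without replicate 2 (0.0549). By fry the fibroblast and epithelial calls were kept (adjusted p = 0.0435 for both), the interferon, p53 and leukocyte calls ended (0.097 each), and ECM receptors were higher (0.0435), where camera gave 0.131, or 0.0499 with GC and length offsets. In all, 117 genes passed, 73 higher and 44 lower. The count fell to 57 and 51 without single-exposure replicates 1 and 2 and to 63, 54 and 68 without multiple-exposure replicates 1, 2 and 3. It was 0 with only the groups compared in edgeR (804 at an unadjusted p under 0.05), where ITGA4 had an adjusted p of 0.0745, while DESeq2 called 324.

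At passages 30 and 10 the regimes differed in few genes. At passage 30 edgeR called 4, here named after their values were seen: EYA2, a transcription cofactor gene (1.98 ± 0.616 CPM in single-exposure cells, log2 fold change -4.55, adjusted p = 0.000399), COBLL1, an actin-related gene (-3.05, adjusted p = 0.012), and ADAM23, a disintegrin gene (-2.93, adjusted p = 0.0491), were lower in multiple-exposure cells. The kinase gene CDK15 was higher (1.93, adjusted p = 0.034). At passage 10, 13 were called and all were lower in multiple-exposure cells, among them, also chosen after their values were seen, EYA2 (-4.54, adjusted p = 0.000119), COL1A2 (15.9 ± 3.38 against 1.81 ± 0.622 CPM, -3.13, adjusted p = 0.00225), the cell surface receptor gene CDON (-1.78, adjusted p = 0.00637), MMP2 (-1.25, adjusted p = 0.00699) and the protease gene BACE2 (-1.57, adjusted p = 0.0113). ADAM23 was the single gene lower at all 3 passages (log2 fold change -3.56, -2.93 and -3.87 at passages 10, 30 and 50), where independent lists would give 3.4e-05 genes. That shared call was kept only without single-exposure passage 50 replicate 1, or multiple-exposure passage 10 or passage 30 replicate 2, and was lost without any other library (0 genes). The passage 30 count was 2 without each single-exposure replicate, 1 without multiple-exposure replicate 1 or 3, and 187 without replicate 2 (143 higher). The passage 10 count was 6 and 7 without single-exposure replicates 1 and 3, and 5, 5 and 2 without multiple-exposure replicates 1, 2 and 3. With only the groups compared edgeR called 962 (541 higher), and 0 at passage 30 (1260 at an unadjusted p under 0.05). DESeq2 called 46 (38 higher) at passage 30 and 53 (13 higher) at passage 10. The preset set test passed 12 lists at passage 30 and 10 at passage 10, and none of them passed with an estimated correlation (lowest adjusted p = 0.106 and 0.184). By fry 3 of the 12 were kept, ECM receptors (0.00934), their ligands and fibrillar matrix genes (0.0235 each), all higher in multiple-exposure cells at passage 30. Of the 10, fibroblast markers were kept (0.0265), lower in these cells at passage 10.

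Within single-exposure cells, the comparison of passage 50 with passage 10 asks how the cells changed over further culture. IGF2, a growth factor gene, rose from 0.761 ± 0.229 to 15 ± 1.38 CPM (log2 fold change 4.29, SE 0.37, adjusted p = 3.99e-06), and ADCY1, an adenylate cyclase gene, rose by 2.95 (adjusted p = 0.000241). Fibronectin, FN1, rose from 1700 ± 291 to 3630 ± 363 CPM (adjusted p = 0.00277) and THBS2 from 244 ± 51.2 to 473 ± 10.9 CPM (adjusted p = 0.00361). COL1A2, which encodes the second chain of type I collagen, fell from 15.9 ± 3.38 to 0.656 ± 0.295 CPM (-4.58, SE 0.47, adjusted p = 3.48e-05), as did the desmosomal cadherin gene DSC3 (19 ± 5.94 to 4.01 ± 1.2 CPM, adjusted p = 0.00712). In all, 107 genes passed, 26 higher and 81 lower, and in 97 of them the mean at passage 30 lay between the others. These genes were chosen for their gap between passages 10 and 50, which favours a mean in between. The share that chance would give was not computed, so the count does not show a gradual change. Interferon-stimulated genes fell as a list (2 of 45 lower, 10 adjusted over the list alone; adjusted p = 4.1e-06, and adjusted p = 0.328 with an estimated correlation). HERC5 was at -1.79 (adjusted p = 0.0386), a call that ended without any of the 6 libraries (0.0548 to 0.185). Cholesterol synthesis genes rose as a list (0 of 25 members, 0 adjusted over the list alone; median 0.55, adjusted p = 1.79e-05, and adjusted p = 0.824 with an estimated correlation). Passage 10 replicates 1 and 2 were lower (-0.15 and -0.57) than the passage 50 libraries (0.65, 0.64 and 0.62), while passage 10 replicate 3 (0.75) was above them all, and fry gave an adjusted p of 0.642. Fibrillar matrix genes rose as well (1 of 44, 5 adjusted over the list alone; adjusted p = 0.00538, and adjusted p = 0.328 with an estimated correlation). The fibrillar call ended without passage 10 replicate 1 (0.0647), with GC and length offsets (0.0887) and by fry (0.0605), and the interferon call by fry (0.0539). Epithelial genes were lower by fry (3 of 29 lower, 4 adjusted over the list alone; adjusted p = 0.0209, against 0.143 by camera), and passed camera without passage 10 replicate 2 (0.0365) or passage 50 replicate 1 (0.0205). The gene count was 55, 38 and 66 without passage 10 replicates 1, 2 and 3, 67 and 48 without passage 50 replicates 1 and 2, 4 with only the groups compared and 251 by DESeq2. The offsets that were not centred gave 67 higher and 114 lower.

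In multiple-exposure cells, the comparison of passage 50 with passage 10 showed a loss of epithelial and a gain of fibroblast and fibrillar matrix transcripts. The separate list of mesenchymal genes did not pass (0 of 34 higher and 1 lower, 3 and 1 adjusted over the list alone; adjusted p = 0.105). Epithelial junction and keratin genes fell as a list (3 of 29 lower and none higher, 8 adjusted over the list alone; adjusted p = 6.34e-07, and adjusted p = 0.000696 with an estimated correlation). DSC3 went down from 38.4 ± 10.7 to 3.98 ± 0.447 CPM (-3.27, SE 0.40, adjusted p = 0.000287) and the claudin gene CLDN7 down (-1.73, adjusted p = 0.0053). Fibroblast markers rose (2 of 7 higher, 5 adjusted over the list alone; adjusted p = 1.4e-10, and adjusted p = 0.00528 with an estimated correlation). COL1A1 went from 639 ± 136 to 1810 ± 186 CPM (log2 fold change 1.5, adjusted p = 0.000829). Fibrillar matrix genes rose (6 of 44, 10 higher and 4 lower adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.0178 with an estimated correlation). The largest change among them was that of periostin, POSTN, a matricellular protein (0.151 ± 0.145 to 15.8 ± 7.5 CPM, 6.65, SE 0.85, adjusted p = 0.000335). POSTN also passed upwards between passages in single-exposure cells. p53 targets fell as a list (1 of 30, 8 adjusted over the list alone; adjusted p = 3.68e-08, and adjusted p = 0.0178 with an estimated correlation). CDKN1A at -1.04 (adjusted p = 0.111) and MDM2 at -1.08 (adjusted p = 0.065) were short of the threshold. Both passed by DESeq2 (0.0346 and 0.0075) and without passage 10 replicate 2 (0.023 and 0.0491), and CDKN1A without passage 50 replicate 2 (0.0495). ECM receptors rose (2 of 26, 2 adjusted over the list alone; adjusted p = 0.000147, and adjusted p = 0.00699 with an estimated correlation) and so did their ligands (1 of 37, 5 adjusted over the list alone; adjusted p = 0.000246, and adjusted p = 0.181 with an estimated correlation), though neither is independent evidence for the pathway named in the study's title. ITGA4 rose from 3.36 ± 0.195 to 20.1 ± 1.5 CPM (2.58, adjusted p = 0.000426). The pathway as the deposited table annotates it had 3 of 61 genes higher (adjusted p = 0.000105, and adjusted p = 0.0993 with an estimated correlation). It also passed between the regimes at passage 30 (no gene past the test, adjusted p = 6.6e-05, and adjusted p = 0.542 with an estimated correlation). It did not pass in any comparison with the control (0.085 to 0.785), between the regimes at passages 50 and 10 (0.935, and 0.18 with the direction down), between single-exposure passages (0.582) or in the interaction (0.126). Of 19 annotated pathways that passed between multiple-exposure passages, 7 also did with an estimated correlation. These were gap junction (adjusted p = 0.0268), dilated cardiomyopathy (0.035), focal adhesion and phospholipase D signalling (0.0387 each), melanogenesis (0.0388), and Hedgehog signalling and platelet activation (0.0411 each), all upwards.

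**Figure D4:**
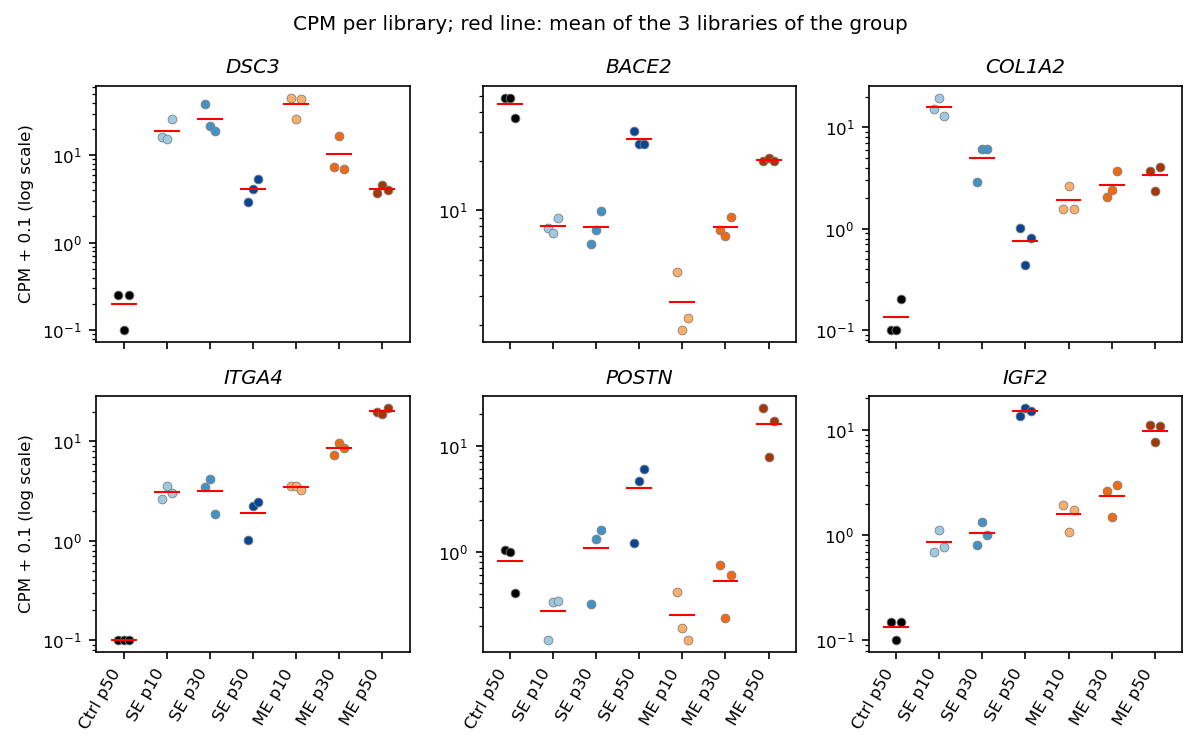
CPM + 0.1 on a log axis for 6 genes in each library (points), with the mean of the 3 libraries as a red line. DSC3 is lower and BACE2 and IGF2 are higher at passage 50 than at passage 10 in both regimes, COL1A2 falls only in single-exposure cells (interaction adjusted p = 0.000445), and ITGA4 rises only in multiple-exposure cells (0.00403).

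Other lists passed in multiple-exposure cells only with the preset correlation, and by fry their adjusted p was 0.0641 to 0.402. Hypoxia and glycolysis genes, cholesterol synthesis genes, NRF2 genes and histone genes rose (0 of 36, 0 of 25, 1 of 29 and 0 of 14 members past the test; 0, 0, 2 and 3 adjusted over the list alone) at adjusted p = 4.55e-07, 1.68e-06, 0.00795 and 0.00795, with adjusted p = 0.239, 0.343, 0.239 and 0.343 with an estimated correlation. The unfolded protein response fell (0 of 30, 0 adjusted over the list alone; 0.000147, and adjusted p = 0.211 with an estimated correlation). The secretome list was lower (1 of 33 lower; 3 higher and 2 lower adjusted over the list alone; 0.038, and adjusted p = 0.552 with an estimated correlation). At passage 10 replicates 1 and 3, and at passage 50 replicate 2, had high secretome levels (1.00, 0.98 and 0.95 on a log2 scale centred on all libraries, against 0.57, 0.01 and -0.01 in the other libraries of these groups) and low cholesterol synthesis levels (-0.76, -0.90 and -0.86 against -0.17, 0.53 and 0.62). Passage 50 replicate 2 did not share the fall of the unfolded protein response (0.29 against -0.51 and -0.44, with 0.29, 0.48 and 0.35 at passage 10) or the rise of histone genes (-0.88 against 0.42 and 0.43, with -0.98, -0.07 and -0.84). For p53 targets it was at -0.04 against -0.44 and -0.43, with 0.48, 0.08 and 0.49 at passage 10. The histone call ended without passage 50 replicate 1 (0.0987) or 3 (0.0538), the NRF2 call without passage 10 replicate 1 (0.0531), the ligand call without passage 50 replicate 2 (0.0784), and the secretome call without passage 10 replicate 1 (0.0576) or passage 50 replicate 1 or 3 (0.146 and 0.168), and with GC and length offsets (0.0671). Without a low-count filter the histone and secretome calls ended (0.122 and 0.0605). In 143 of the genes that passed, the mean at passage 30 lay between the others, which choosing genes for their gap between passages again favours. By gene, 148 passed, 83 higher and 65 lower. The majority turned without passage 10 replicate 2 (54 higher, 85 lower) and passage 50 replicate 2 (105 and 116), and with limma-trend on log2(FPKM + 0.1) (80 and 87) and log2(FPKM + 1) (68 and 73). The count was 57 and 45 without passage 10 replicates 1 and 3 (29 higher and 28 lower, and 22 and 23), 57 and 64 without passage 50 replicates 1 and 3, 84 with only the groups compared, 332 by DESeq2, and 345 without single-exposure replicate 1 at passage 50, which shares the fit.

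The passage changes of the regimes overlapped in 24 genes: 7 rose in both, 16 fell in both and 1 moved in opposite directions, where independent lists would share 0.2 and 0.4 (r = 0.224 across genes). POSTN, IGF2, ADCY1 and BACE2 were among those that rose, and DSC3 among those that fell. The test of the difference itself called 31 genes, 23 with the more positive change in multiple-exposure cells and 8 with the more negative. COL1A2 fell with passage in single-exposure cells and went from 1.81 ± 0.622 to 3.29 ± 0.911 CPM in multiple-exposure cells (interaction log2 fold change 5.44, SE 0.62, adjusted p = 0.000445). ITGA4 was at 2.97 ± 0.49 and 1.8 ± 0.775 CPM in single-exposure cells and rose in multiple-exposure cells (3.30, SE 0.46, adjusted p = 0.00403). MMP2 (1.86, adjusted p = 0.00438) and TMEM40 (-2.42, adjusted p = 0.00464) differed as well. As lists, fibroblast markers (1 of 7, 4 adjusted over the list alone; adjusted p = 5.42e-10, and adjusted p = 0.0159 with an estimated correlation) and ECM receptors (1 of 26, 2 adjusted over the list alone; adjusted p = 0.00257, and adjusted p = 0.0394 with an estimated correlation) had the more positive change in multiple-exposure cells, and epithelial genes the more negative (0 of 29, 1 adjusted over the list alone; adjusted p = 0.0221, and adjusted p = 0.0489 with an estimated correlation). These 3 lists passed fry too (0.00215, 0.00361 and 0.0314). With the preset correlation alone, p53 targets (2.08e-05) and the unfolded protein response (0.0276) had the more negative change, and hypoxia and glycolysis genes (0.00241) and interferon-stimulated genes (0.0313) the more positive. No member of these passed (2 p53 targets adjusted over the list alone, 0 in the others), and their adjusted p was 0.0781 for p53 targets and 0.724 for the others with an estimated correlation. The count of 31 was 16, 8 and 15 without single-exposure passage 10 replicates 1 and 2 and passage 50 replicate 2, 9 and 10 without multiple-exposure passage 10 replicates 1 and 3, 14 without each passage 50 replicate of that regime, 16 with only these groups in the fit and 131 by DESeq2. The offsets that were not centred gave 46 higher and 27 lower.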

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

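The tests of a passage difference and of chromosome 22, and the comparison of neighbouring genes with comparisons that lack the control, were chosen after their results were seen, as were the offsets for GC content and length and the surrogate variables.

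The change from passage 10 to passage 50 differed between the regimes in 31 genes by the interaction test, which is what singled these results out. The interaction log2 fold changes were 5.44 for COL1A2, 3.30 for ITGA4, 1.86 for MMP2 and -2.42 for TMEM40, and no single library decided these calls. PPM1L (2.32, adjusted p = 0.0214), CDON (1.96, 0.0317), HHAT (-1.50, 0.0366) and DNAJA4 (-1.25, 0.0224) lost theirs when libraries were left out. PPM1L did so without single-exposure passage 10 replicate 2 (0.0709), multiple-exposure passage 10 replicates 1 and 3 (0.0728 and 0.0864) and passage 50 replicate 2 (0.0608). CDON lost it in 7 of the 12 omissions (0.057 to 0.11), DNAJA4 in 8 (0.0508 to 0.0989) and HHAT in 10 (0.061 to 0.151). In 1 of 100 splits drawn from 200 possible ones, the real split itself, there were as many calls. The highest other gave 19 against the real 31, so among the splits drawn the real assignment gave the most calls by edgeR. Splits that mix the regimes raise the spread within a group wherever the regimes differ, which lowers their calls. Counts at an unadjusted p under 0.05 were not taken for these splits. The splits exchange libraries between regimes within a passage, so they do not separate an interaction from a difference at 1 passage. If the libraries of a group came from 1 culture, chance differences between cultures are not excluded.

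The control libraries differ from all irradiated libraries. A difference in passage label is excluded as the whole cause. Against the control, calls at passage 50, where the label matches, were 1.21 times those at passage 10 in single-exposure cells. In multiple-exposure cells they were 0.79 times those at passage 10. Time in culture was not tested. GC content or transcript length as the whole cause is excluded, since 84.8% of the calls of single-exposure cells at passage 50 were called again with these offsets. A shift shared by neighbouring genes, as a broad copy number change would give, is excluded as the whole cause as well. Of these calls 57.1% were at least 2-fold, and 49.8% still were after taking off the local median of neighbouring genes. Copy number changes of few genes, or their effects on genes elsewhere, are not covered by this test. Irradiation stays open and untested as a biological difference. A control culture that differs from the others in origin, handling or sequencing stays open too. It cannot be told apart from the groups without batch labels.

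Whole chromosomes shift between the control and the irradiated libraries, and 19 of the 26 chromosome tests that passed in the 5 main comparisons were in comparisons without the control. These tests used a preset correlation between genes: with an estimated one, none of those against the control passed, and 4 of all 115 did (adjusted p = 0.577 to 0.861 for the chromosomes named here at passage 50), so the shifts themselves rest on that setting. GC content or length is excluded as the whole cause for chromosome 5, whose median was still -0.35 with these offsets, against -0.47 without, in single-exposure cells at passage 50. Chromosomes 3 and 14 also passed with the offsets (adjusted p = 0.000891 and 0.0403). GC content or transcript length bias of chromosome 22 stays open: its median went from 0.44 to 0.2 and its call ended (0.0513). A copy number difference between the control and the irradiated cultures stays open as well. Neighbouring genes shared their shift (Spearman 0.273, highest of 1000 shuffles 0.026), but they did so in comparisons without the control too, up to 0.317 between passages 50 and 10 of single-exposure cells and 0.251 between the regimes at passage 50. With the offsets the values were 0.228 against the control and 0.126 and 0.102 in these comparisons. DNA was not analysed here, and irradiation as the origin of the shifts was not tested.

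Libraries within the multiple-exposure groups and the single-exposure group at passage 30 lie apart along an axis of cytokine, amino acid response and cholesterol synthesis genes. Cell cycle and histone genes were lower in the libraries of these groups that were high for cytokine genes. Cell cycle levels (centred log2 scale) were -0.13 in single-exposure passage 30 replicate 1, against 0.28 and 0.29 in the others. In multiple-exposure cells they were -0.24 and -0.34 against 0.19 at passage 10, and -0.46 and -0.42 against 0.05 at passage 30. At passage 50, replicate 2 was at -0.4, against 0.21 and 0.22. These lists were not part of the tests below. For an exchange of labels between replicates 2 of multiple-exposure passages 30 and 50, a scale of passage-dependent genes was used. Passage 50 replicate 2 lay at 0.69, above all passage 30 libraries (0.41 to 0.57, replicate 2 at 0.43), which speaks against an exchange. It also lay below passage 50 replicates 1 and 3 (0.98 and 1.02), which set the upper end of the scale. The passage 50 controls lay at 0.41 to 0.53, so the scale does not follow passage alone and cannot exclude an exchange. Subclones with different copy number stay open (neighbour correlation 0.26 of that between irradiated and control cells, between the bounds of 0.25 and 0.5). A difference in culture state stays open too: in 4 of 6 groups the library highest for the amino acid response was the lowest for hypoxia and glycolysis genes, where chance gives 2 (exact binomial one-sided p = 0.1). No biological explanation was tested, since the labels give no difference within groups.

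For comparisons of 3 with 3 libraries, 10 splits cannot give a share under 0.05. As many calls as the real split came from 1 of 10 splits in 10 of these 11 comparisons, with 0 calls as the highest other by edgeR. At an unadjusted p under 0.05, however, another split between the regimes at passage 50 held 2773 genes against the real 1840. Between multiple-exposure passages another split held 3219 against 1806. In the rest of these 10 comparisons the real split held the most. The real counts were 4320 and 3891 for single-exposure and multiple-exposure cells against the control at passage 50, 3571 and 4930 at passage 10, 3908 and 5012 at passage 30, 117 and 13 between the regimes at passages 50 and 10, and 107 and 148 between passages 50 and 10 in single-exposure and multiple-exposure cells. Between the regimes at passage 30, 2 of 10 splits did so. The split of single-exposure replicate 1 with multiple-exposure replicates 1 and 3 against the rest gave 1633 calls where the real one gave 4, which points to a structure of the samples, the axis described above.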

How the results depend on the processing

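The offsets for GC content and length, the surrogate variables and the fit without single-exposure replicate 1 at passage 50 were chosen after seeing the data. Except where construction is named, the cause of a change was not tested.

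Of 315 results for named genes, direction and side of the threshold were kept by 312 with RLE normalization, 308 with DESeq2 (5 gained a call), 308 without a low-count filter, 313 with the 1 CPM filter, 299 with either FPKM pseudocount, 296 with the offsets, 293 with offsets not centred, 294 with surrogate variables and 254 of 313 with only the groups compared (55 lost a call), where fewer libraries estimate the spread. Leaving out 1 library kept 1804 of 2072, with 261 calls lost and 7 gained. ITGAV in single-exposure cells at passage 50 against the control turned from -0.03 to 0.44 with the offsets, 0.31 with offsets not centred and 0.28 with surrogate variables.

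DESeq2 gave 324 genes for multiple against single exposure at passage 50, 46 at passage 30, 53 at passage 10, 251 and 332 for passage 50 against 10 in single-exposure and multiple-exposure cells, 131 for the interaction and 2 for genes shared by all 3 passages. Only the groups compared gave 2737 for single-exposure cells against the control at passage 50 and 6734 at passage 10. Between the regimes it gave 0, 0 and 962 at passages 50, 30 and 10 (804, 1260 and 3799 at an unadjusted p under 0.05 by edgeR), then 4 and 84 between passages, 16 for the interaction and 0 for all 3 passages. The shared gene was also lost (0) with RLE normalization and with log2(FPKM + 1).

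With the offsets the counts were 223 between regimes at passage 50, 24 at passage 10, 180 and 277 between passages, and 84 for the interaction. Not centred they were 218, 181, 279 and 73 for passage 50, the passages and the interaction, and 5566 for single-exposure cells at passage 10 against the control. With 2 surrogate variables they were 6537 and 7003 against the control at passage 50, 6964 and 7208 for single-exposure cells at passages 10 and 30, 659, 21 and 40 between regimes at passages 50, 30 and 10, 545 and 1066 between passages, 638 for the interaction and 5329 for the overlap. The fit without single-exposure replicate 1 at passage 50 gave 7 at passage 30 between regimes and 345 for multiple-exposure passages.

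The ranges here cover omission of libraries of the groups compared. Other libraries share the fit, and leaving out single-exposure replicate 1 at passage 50 moved the count of multiple-exposure passages beyond its range. Against the control, counts ranged over 3342 to 5031 and 3004 to 3364 at passage 50 (single, multiple). They were 2817 to 2979 and 3675 to 4920 at passage 10, and 3033 to 3437 and 3700 to 5867 at passage 30. Between regimes they ranged over 51 to 114, 1 to 187 and 2 to 9 at passages 50, 30 and 10, between passages over 38 to 105 and 45 to 221, for the interaction over 8 to 36, for the overlap over 2332 to 3442, and for all 3 passages over 0 to 1.

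Of 105 list tests 32 passed, 28 to 36 with 1 library left out and 5 with an estimated correlation. Direction and side were kept by 105 with RLE normalization, 94 without a low-count filter, 97 with the offsets and 76 with fry. Of 115 chromosome tests 26 passed, 18 to 34 with 1 library left out, 16 with the offsets and 4 with an estimated correlation. Without single-exposure replicate 1 at passage 50 chromosomes changed sign between the regimes (13, 17, 18 and 19, adjusted p = 0.000853, 0.923, 0.923 and 0.0397). Over all omissions their adjusted p ranged over 0.000853 to 0.971, 0.000483 to 0.923, 0.000515 to 0.923 and 0.000291 to 0.0956. Chromosomes 4, 5, 13 and 19 did so between single-exposure passages (0.922, 0.922, 0.246 and 0.773; ranges 4.15e-05 to 0.922, 0.00789 to 0.922, 0.000527 to 0.246 and 7.85e-06 to 0.773). With the offsets, chromosome 19 between regimes (0.466) and chromosome 13 between single-exposure passages (0.807) did.

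With a replicate block, 2 genes were called between regimes at passage 30 and 0 at all 3 passages. The numbers do not pair libraries: over 63 pairs with the same number, deviations from the group mean correlated from -0.61 to 0.62 (mean -0.008), and 7 of 21 libraries matched best with their own number. In depth, 2-fold changes were called for 9% of simulated genes in the interaction, so a low count there does not show that few genes differ.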

Other observations

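The criteria for the genes below, and the test on them, were chosen after seeing the data.

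Some genes were present on 1 side only, with at most 3 counts in every library of the other side. Genes of chromosome Y and XIST were left out of this search. In every irradiated library at 1 CPM or more, but not in the control, were 140 genes, of which 18 reached 10 CPM. The highest means were those of NRIP3 (80.7 CPM), ZNF532 (59.8 CPM), CCL5 (52.8 CPM) and EVPL (34.6 CPM). In every control library but in no irradiated one were 19 genes, of which 2 reached 10 CPM, led by GPC4 (26.4 CPM) and ZNF704 (15.2 CPM). Chromosome X held 11 of the 140 (7.9%) and 5 of the 19 (26.3%), and 446 of all 13361 genes tested (3.3%). By Fisher's exact test, two-sided, 16 of these 159 genes were on chromosome X against 430 of the 13131 other tested genes with a position off chromosome Y (odds ratio 3.30, p = 8.84e-05). Genes of 1 chromosome are not independent, so this p describes these genes only.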
